A study of Zea mays with 8 samples.

How the data were processed

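The series measured gene expression in maize roots on 8 Affymetrix maize arrays, 1 biotin-labelled cRNA per array. Plants of the wild type F2 and of the brown midrib mutant bm4 were either inoculated with the arbuscular mycorrhizal fungus Glomus intraradices, at 6000 spores per plant, or left as controls. Per the labels' protocols, the plants were 7 weeks old, were grown on a medium low in phosphate at 24 °C with 12 h of light, and RNA came from frozen roots. The 4 groups (F2 control, F2 mycorrhizal, bm4 control and bm4 mycorrhizal) had 2 arrays each. The labels do not say whether the arrays of a group came from separate plants, separate pools or 1 extract divided, so p-values measure only the spread between these samples. The labels also do not say how closely the bm4 line is related to F2 outside the mutated gene, and they give no level of root colonization.

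The deposited table holds log2 expression values per probe set, made by the authors with GCRMA in R 2.6.2, per the submitters' processing notes. GCRMA corrects the background, normalizes the arrays to equal quantiles and summarises the probes of each set. No scanner files were available, so the background correction and summarisation could not be varied. The values lay between 1.45 and 15, with array medians between 5.68 and 5.8. Each array had between 10306 and 10376 probe sets at 4 or more on the log2 scale. Signal near the lower end of the scale is background, and the number of arrays limits the precision.

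Of the 17734 probe sets in the table, 179 control probe sets were left out. Among the 17555 maize probe sets, 10648 reached 4 on at least 2 arrays and were tested, and 6907 did not. Gene names came from the platform annotation, which is old and names few genes. It gave 1452 probe sets exactly 1 gene (8.27% of the maize probe sets), 1 probe set several genes, and 16102 none. A probe set without a name here may still measure a known gene. The gene identifiers of 1377 probe sets were found in the RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0, which was used for names only. Usable names remained for 1267 probe sets of 976 genes. No probe set carried the name of bm4, of the lignin methyltransferase gene bm3 or of the mycorrhiza phosphate transporter gene pht6, so no value can be given for them.

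Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 4 residual and 3.38 prior degrees of freedom. The 5 main contrasts were: inoculation within F2, inoculation within bm4, bm4 against F2 in control plants, bm4 against F2 in mycorrhizal plants, and the interaction, which is the response of bm4 minus the response of F2. The mean response to inoculation and the mean genotype difference were tested as well. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested probe sets within a contrast, and a probe set passed at an adjusted p under 0.05. Errors written after ± are standard errors of the fit on the log2 scale unless called SD. Fold values are 2 raised to the log2 difference. A group whose arrays were all under 4 was treated as not above background, and a fold against it is given as "at least": the mean of the brighter group against the dim group's mean of, per array, the higher of 4 and its own value. Measured log2 differences against such groups are those of the fit. On 1 of the 2 arrays only, the level was under 4 for ciszog1, gst30, xet1, sut1 (also under 4 on both bm4 control arrays) and the 21.8-fold probe set of pdk1 in F2 control plants, for psy2 in bm4 control plants and for prpl35-1 in bm4 mycorrhizal plants.

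Lists of genes for 26 functions were fixed beforehand from symbols and descriptions, and 25 of them had a member on the array. The tables held symbols and synonyms but no descriptions, so members were found by symbol alone. The lists covered monolignol biosynthesis; lignin polymerisation; folate and methyl cycle; cellulose, callose and hemicellulose synthesis; wall loosening; mycorrhiza markers; phosphate; nitrogen; defence; benzoxazinoids; isoprenoids, carotenoids and strigolactones; lipids; sugar transport and sucrose cleavage; aquaporins; jasmonate; auxin; ethylene, gibberellin and abscisic acid; proteases; metal homeostasis; photosynthesis; endodermis, suberin and root hairs; cell division; ribosomal proteins; heat shock and folding; anaerobic genes; and detoxification. The list of endodermis, suberin and root hair markers had no member. Each gene was represented by its probe set with the highest mean, and 18 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01. Its p-values were adjusted over the 90 tests of 18 lists in the 5 contrasts. Of these, 23 passed with the preset correlation and 0 with a correlation estimated for each list.

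Genes named in the text were chosen by a rule set before the data were examined. For each of the first 4 contrasts the rule took the 6 named genes with the largest rise and the 6 with the largest fall, among those that passed and whose arrays did not overlap between the groups. It added up to 3 passing members from each of the lists for mycorrhiza markers, monolignols and phosphate, and from up to 6 further lists in the order of their camera p. For the interaction it took up to 10 genes, and for the 2 mean contrasts 4 in each direction. The cinnamyl alcohol dehydrogenase gene bm1 was named whatever its result. Other members of the lists appear as examples of their list and were chosen after their values were seen. The contrasts, lists, tests and most alternatives were fixed at the same time as this rule. A gene with several probe sets can have more than 1 value, and 107 genes had several. In the comparison of control plants, 45 of them had at least 1 probe set that passed, 19 had passing and other probe sets, and 1 had calls in both directions.

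The alternatives were a different filter on dim probe sets (none, or 6 on at least 2 arrays), eBayes without the trend or with robust estimation, quantile normalization again, centring each array on its median, the replicate number as a block, array weights, only the 4 arrays of the groups compared, and leaving out each array in turn. For lists they also included an estimated correlation and the mean of a gene's probe sets. Leaving out probe sets marked as cross-hybridising, and leaving out list members matched through another gene's name, were added after the data were seen. When 1 array was left out, the remaining array of its group was assumed to vary like the other groups.

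The fit was tested on simulated data with 200 changed probe sets among 10648. Each probe set had its real mean over all arrays and its fitted spread, so the genotype differences were left out. For inoculation in F2 it recovered 23.9% of 67 probe sets changed 1.5-fold, 80.6% of 67 changed 2-fold and 100% of 66 changed 4-fold, and it called 14 of 10448 unchanged ones. For the interaction it recovered 5.97%, 35.8% and 95.5% at the same sizes, and called 9 unchanged ones. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.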

Results

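The data are 8 arrays of maize roots, with 2 arrays in each of 4 groups: F2 control, F2 mycorrhizal, bm4 control and bm4 mycorrhizal plants. The bm4 mutant belongs to the brown midrib class, whose lignin and cell walls are altered, and the bm4 gene encodes folylpolyglutamate synthase, an enzyme of folate metabolism. The labels name as aims the part played by the cell wall in mycorrhizal symbiosis, the gene regulation that accompanies it, the mycorrhizal phenotype of bm4, and genes worth following up. The RNA yield per sample ranged from 34.22 to 70.09 µg, and 20 µg of cRNA was used. Values of the arrays of 1 group correlated with r between 0.983 and 0.99 across probe sets, which are not independent replicates. The SD of the difference between the arrays of a group was 0.40 in F2 control, 0.34 in F2 mycorrhizal, 0.32 in bm4 control and 0.31 in bm4 mycorrhizal plants.

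Genotype separated the arrays most. The first principal component held 61.7% of the variance and placed the F2 arrays between -41.7 and -31.8 and the bm4 arrays between 30 and 41.8. The second held 19.4% and separated control from mycorrhizal plants, between 25.1 and 27.4 against -29 and -27.3 in F2, and between 12.6 and 12.7 against -11.3 and -10.3 in bm4. A sign of RNA quality, the 3′ minus 5′ signal of control genes, was smaller in bm4 for actin, though it did not pass after adjustment. A smaller value is a smaller excess of 3′ signal, not a sign of poorer RNA. The actin signal near the 3′ end minus that near the 5′ end was 7.54 ± 0.20 (SD, n = 4) in F2 and 6.84 ± 0.34 (SD, n = 4) in bm4, a difference of -0.70 with an exact two-sided permutation p of 0.0286 and an adjusted p of 0.0858 over 3 such measures. The same measure gave differences of -0.01 for gapdh and -0.12 for ef1a, with exact permutation p-values of 0.6 and 0.657.

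The first comparison asked which genes responded to the fungus in wild-type roots. In F2, inoculation raised ciszog1, a cis-zeatin O-glucosyltransferase that stores the hormone cytokinin, by 4.42 ± 0.39 on the log2 scale (21.4-fold, adjusted p = 0.000933, n = 2 arrays per group here and in every comparison below). The glutathione transferase gene gst6 rose 17.7-fold (4.14 ± 0.27), the terpene synthase gene tps6 11.9-fold (3.58 ± 0.50) and the phytoene synthase gene psy2, which starts carotenoid synthesis, 4.91-fold (2.29 ± 0.28). The genes pht7 and pht1 of phosphate transport rose by 1.44 ± 0.25 and 0.77 ± 0.12. The largest falls among named genes were those of the nitrate transporter gene nrt2, which fell by 1.76 ± 0.39, of PEAMT, which fell by 1.59 ± 0.36, and of INO1, an inositol phosphate synthase of the first step towards inositol, which fell by 1.56 ± 0.30 (at least 2.12-fold). Their adjusted p-values were 0.0455, 0.0477 and 0.0266.

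In all, 609 of 10648 probe sets passed in F2, 438 higher and 171 lower, and 288 of the higher and 54 of the lower ones differed at least 2-fold. The higher ones included 48 named genes and the lower ones 12. Among those not yet mentioned, Agp2 of starch synthesis rose 4.88-fold and sip1 4.35-fold at its brighter probe set. The other sip1 probe set had a value of 0.92 and did not pass (adjusted p = 0.272). The genes gst42 and CYP88A1, the latter of gibberellin synthesis, were under 4 in F2 control plants and rose at least 2.63-fold and 1.32-fold. The genes nas1 (nicotianamine synthase, a metal chelator pathway) and IIG2 fell by 1.23 ± 0.26 and 0.99 ± 0.18, the latter to a level under 4 (at least 1.44-fold). The 2 probe sets with the largest rises had no gene name here, and went from 2.38 to 11.96 and from 2.28 to 11.49 in F2. The 2 largest falls among unnamed probe sets were -2.39 ± 0.39 and -1.93 ± 0.33.

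Genes of isoprenoid and carotenoid metabolism rose together in F2. Of 9 measured members of their list 7 rose, 0 fell and 2 did not pass, and adjusted over the list alone 8 rose and 1 fell. The camera test gave an adjusted p of 1.13e-05, and adjusted p = 0.335 with an estimated correlation. Besides tps6 and psy2, the rising members were the carotenoid cleavage dioxygenase gene CCD1 (1.43 ± 0.13), the carotenoid desaturase genes zds1 (1.43) and Pds (0.89), and Hds1 (1.22) and dxr (0.91) of the plastid pathway to isoprenoid precursors. The other 2 members had values of 0.60 for hdr10 and -0.55 for dxs1, adjusted p = 0.214 and 0.216.

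**Figure D1:**
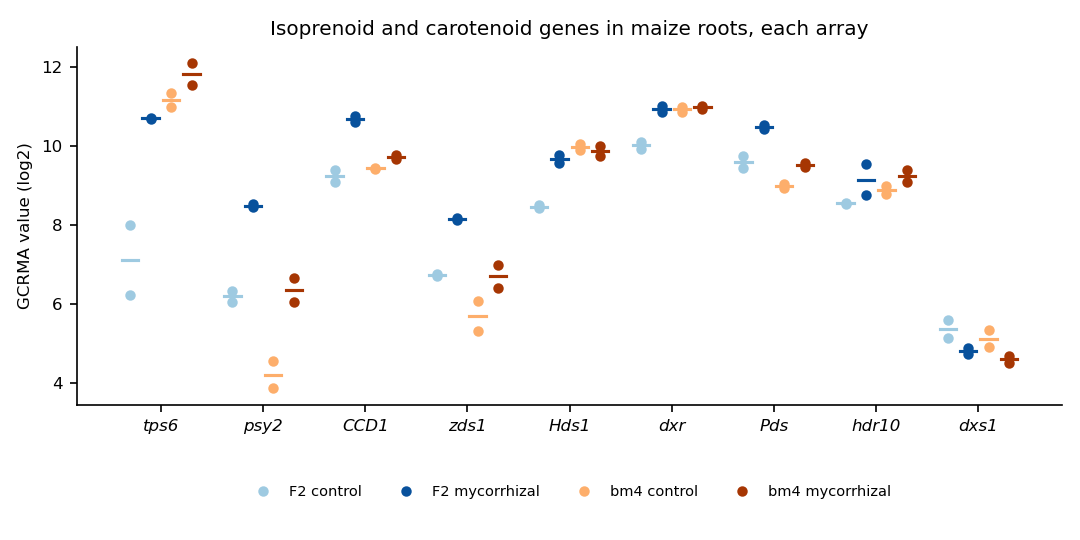
GCRMA values on the log2 scale (vertical axis) of 9 isoprenoid and carotenoid genes (horizontal axis), with 1 point per array in 4 groups and a bar at each group's mean. In F2, mycorrhizal arrays lay above control arrays for the 7 genes that rose, and psy2 went from a mean of 6.19 to 8.49 in F2 and from 4.22 to 6.36 in bm4.

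Sugar genes and detoxification genes also rose as groups in F2. Of 7 sugar transport and sucrose cleavage genes, 3 rose and 4 did not pass, or 4 rose adjusted over the list alone: the sucrose transporter gene sut1 by 1.90 ± 0.22 and the sucrose synthase genes sh1 by 1.21 ± 0.15 and sus1 by 0.83 ± 0.11. Of 32 detoxification genes, 5 rose, 0 fell and 27 did not pass, or 8 rose adjusted over the list alone, and these 5 were all glutathione transferases, among them gst30 (1.76 ± 0.13) and gst5 (1.48). Both lists had a camera adjusted p of 0.0161, and adjusted p = 0.429 with an estimated correlation. The sugar list lost its call when probe sets marked as cross-hybridising were left out (adjusted p = 0.0724), an alternative chosen after the data were seen. With the filter at 6 it had an adjusted p of 0.0779, and the detoxification list one of 0.0512. The detoxification call also ended without F2 control array 2 (adjusted p = 0.0599).

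At the preset correlation of 0.01, aquaporins and nitrogen genes were lower as groups in mycorrhizal F2 roots, while their estimated correlations were 0.417 and 0.492. Of 23 aquaporin genes, 1 rose, 2 fell and 20 did not pass, or 2 rose and 9 fell adjusted over the list alone. The members that fell included pip2-5, a plasma membrane water channel, by 0.84 ± 0.19, while a second probe set of PIP1-3 fell by 0.71 ± 0.13. The brighter PIP1-3 probe sets had similar values of -0.72, -0.67 and -0.64 but did not pass (adjusted p = 0.0509, 0.0514 and 0.0574). The member that rose, sip1, was matched by its symbol alone, and it also carries the name Zlp, so it was left out of the list in an alternative chosen after the data were seen. The camera adjusted p was 0.00389, and adjusted p = 0.596 with an estimated correlation. Of 8 nitrogen genes, 2 fell and 6 did not pass, or 6 fell adjusted over the list alone, and these 2 were nrt2 and the glutamine synthetase gene gln5, which fell by 0.54 ± 0.10. The list's adjusted p was 0.0266, and adjusted p = 0.596 with an estimated correlation, and its call ended without F2 control array 2 (0.0636), without F2 mycorrhizal array 1 (0.17) and with the mean of each gene's probe sets (0.0542). A probe set of the asparagine synthetase gene asn1 went against the list and rose by 0.76 ± 0.15, and the brighter asn1 probe set had a value of 0.25.

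Both phosphate genes found by symbol among the tested probe sets, too few for a list test, rose in F2 and are the pht7 and pht1 named above. Of 2 genes on the list of mycorrhiza markers, CYP88A1 rose, and it matched only through the older name d3, which it shares with a strigolactone signalling gene of rice. The other, the symbiosis kinase gene CCamK, had a value of 0.03. The 6 defence genes included 2 that rose, the chitinase gene chn1 (2.19) and PR-1 (2.02), with a camera adjusted p of 0.106 for the list. Of 15 anaerobic genes 3 rose, sh1, sus1 and the enolase gene eno1 (0.42 ± 0.10, adjusted p = 0.05 after rounding), and the list had an adjusted p of 0.0854. Of 6 metal homeostasis genes, nas1 alone fell (list adjusted p = 0.381).

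None of the 5 monolignol genes, which make the building blocks of lignin, passed in F2. All 5 had values below 0, with a list median of -0.26 and an adjusted p of 0.22, and bm1 had a value of -0.31 ± 0.14 (adjusted p = 0.266). No member passed among 6 genes of lignin polymerisation (list adjusted p = 0.941), 10 of cellulose and hemicellulose synthesis (0.355) or 7 of wall loosening (0.941). The same held for 10 of the jasmonate list (0.749), 5 of ethylene, gibberellin and abscisic acid (0.167) and 7 proteases (0.696). It held too for 12 of cell division (0.641), 14 ribosomal proteins (0.183) and 10 of heat shock and folding (0.223). Nor did any pass among the smaller sets of 3 benzoxazinoid, 3 lipid, 3 auxin, 2 photosynthesis and 1 folate or methyl cycle gene.

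The F2 count fell from 609 to 382 without F2 control array 2, to 254 without F2 mycorrhizal array 1, to 348 without F2 mycorrhizal array 2 and to 325 when only the 4 F2 arrays were fitted. These 4 fits gave 75, 22, 99 and 52 lower calls, where all arrays gave 171, and 307, 232, 249 and 273 higher ones, where all arrays gave 438. Of 25 named calls, 12 stayed when any 1 array was left out, among them ciszog1, gst6, gst42, psy2, sut1, CCD1 and sh1, and the other 13 ended without at least 1 array, with adjusted p-values up to 0.239. The call of tps6 ended without F2 mycorrhizal array 1 (adjusted p = 0.0544), as did that of pht7 (0.114), while pht1 lost its call without F2 control array 2 or F2 mycorrhizal array 2 (up to 0.07). The calls of nrt2, PEAMT, INO1, nas1, IIG2, pip2-5, PIP1-3, gln5, asn1 and eno1 each ended without 3 or more of the 8 arrays in turn, and their highest adjusted p-values were 0.131, 0.228, 0.125, 0.146, 0.1, 0.239, 0.144, 0.13, 0.136 and 0.238.

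The next comparison asked for the response to the fungus in the mutant. In bm4, psy2 rose 4.42-fold (2.14 ± 0.28, adjusted p = 0.028), gst6 3.55-fold (1.83 ± 0.27, adjusted p = 0.0477) and ACC1 2.28-fold (1.19 ± 0.14, adjusted p = 0.0214). The glutathione transferase gene gst30, which rose in F2, fell by 0.87 ± 0.13 in bm4 (adjusted p = 0.0434). In all, 52 probe sets passed, 41 higher and 11 lower, with 38 and 8 of them at least 2-fold apart. Only these 4 named genes were among them, and 1262 probe sets had an unadjusted p under 0.05. The 2 unnamed probe sets with the largest rises in F2 had the largest rises here too, from 2.44 to 9.10 and from 2.32 to 8.97.

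Monolignol genes were lower as a group in mycorrhizal bm4 roots, although 0 of the 5 passed on their own. Adjusted over the list alone 3 fell, the list median was -0.31, and the lowest values were those of the cinnamoyl-CoA reductase gene ccr2 (-0.73, adjusted p = 0.128) and of bm1 (-0.58 ± 0.14, adjusted p = 0.164). The camera adjusted p was 0.0108, and adjusted p = 0.494 with an estimated correlation. Of 7 proteases 0 passed, or 5 fell adjusted over the list alone, with see2b at -0.67 and see2a at -0.55. That list had an adjusted p of 0.0113, and adjusted p = 0.522 with an estimated correlation, and its call ended without bm4 control array 2 (0.0802).

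Lists of 4 other kinds were higher in mycorrhizal bm4 roots. Of 9 isoprenoid genes 1 rose, psy2, and 8 did not pass, or 3 rose adjusted over the list alone, with an adjusted p of 0.0266. Of 7 sugar genes 0 passed, or 1 rose adjusted over the list alone, sut1, whose level was under 4 in bm4 control and 4.61 in bm4 mycorrhizal plants (at least 1.53-fold), and the list had an adjusted p of 0.0266. Both had adjusted p = 0.429 with an estimated correlation. Of 15 anaerobic genes 0 passed, or 3 rose and 1 fell adjusted over the list alone, with the alcohol dehydrogenase gene adh1 at 0.73 and gpc4 of glycolysis at 0.92. That list had an adjusted p of 0.0109, and adjusted p = 0.429 with an estimated correlation. Of 7 wall loosening genes 0 passed, or 1 rose adjusted over the list alone, all 7 had values above 0, and the largest were those of the expansin genes expB7 (2.28) and expA3 (0.99). The adjusted p was 0.0258, and adjusted p = 0.43 with an estimated correlation.

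Those 4 calls ended under more of the alternatives than the monolignol one, which ended only with an estimated correlation. That correlation was 0.588 for monolignol genes, against 0.108 for wall loosening, 0.0563 for anaerobic, -0.0129 for sugar and -0.11 for isoprenoid genes. The alternatives therefore do not make the monolignol call the firmest. The isoprenoid call ended without bm4 control array 1 (adjusted p = 0.0716), without bm4 mycorrhizal array 1 (0.0637) and with no filter on dim probe sets (0.0521). The sugar call ended without bm4 control array 2 (0.0656), without bm4 mycorrhizal array 1 (0.0769), with the filter at 6 (0.0884) and without cross-hybridising probe sets (0.0763). The anaerobic call ended without bm4 mycorrhizal array 1 (0.0595). The wall loosening call ended without bm4 control array 2 (0.0529), without bm4 mycorrhizal array 2 (0.194) and with the filter at 6 (0.0512). No member passed in the remaining lists except gst6 and gst30, and those lists had adjusted p-values from 0.0604 for lignin polymerisation to 0.891 for ribosomal proteins.

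The bm4 count moved from 52 to 32 and 33 without F2 mycorrhizal array 1 or 2, to 10 and 13 without bm4 control array 1 or 2, and to 33 and 22 without bm4 mycorrhizal array 1 or 2. It was 17 with only the 4 bm4 arrays, 79 with the filter at 6 and 80 with array weights. None of the 4 named calls stayed in every fit with 1 array left out. The call of gst30 ended in all 8 of these fits, those of gst6 and ACC1 in 6 and that of psy2 in 5. Without bm4 control array 1 psy2 had an adjusted p of 0.147, without bm4 mycorrhizal array 2 gst6 had 0.231 and gst30 0.243, and without bm4 control array 2 ACC1 had 0.135.

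Setting the responses side by side, 31 probe sets rose in both genotypes, where independent lists of 438 and 41 would share 1.69, and 3 fell in both, where 0.177 would be shared. Another 2 passed in opposite directions. The probe sets that rose in F2 had a median change of 1.24 there and of 0.26 in bm4, and 78.1% of them had the same sign in bm4. Those that rose in bm4 had medians of 2.14 in bm4 and 2.23 in F2. Across all tested probe sets, which are not independent, the changes correlated with r = 0.43.

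The interaction tested the difference between the responses itself. In every named gene that passed, the response of bm4 lay below that of F2. The glutathione transferase genes gst30, gst42, gst6 and gst5 had interaction values of -2.63 ± 0.18, -2.51 ± 0.26, -2.31 ± 0.39 and -2.14 ± 0.23, with adjusted p-values of 0.00177, 0.0104, 0.0464 and 0.0123. CYP88A1, with an interaction of -2.16 ± 0.30 (adjusted p = 0.026), was under 4 on every array except those of F2 mycorrhizal plants, where its mean was 4.40, so its change within bm4 was not measured above background. The F2 control level of gst42 was under 4 too, so the size of these 2 interactions rests on background signal. The chitinase gene chn1 (-2.13 ± 0.35), the plastid ribosomal protein gene prpl35-1 (-2.05 ± 0.33), NIP1-1 (-1.66 ± 0.27), Hds1 (-1.31 ± 0.19) and CCD1 (-1.13 ± 0.18) passed as well. The interaction of bm1 was -0.27 ± 0.20 (adjusted p = 0.673).

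In all, 121 probe sets passed, 12 above 0 and 109 below, and 13 named genes were among the latter. In 53 of the 109, F2 control plants were the group farthest from the other 3, in 48 F2 mycorrhizal plants were, and in 8 bm4 control plants were. As an example of the first kind, Hds1 had a mean of 8.46 in F2 control plants and of 9.68, 9.97 and 9.88 in F2 mycorrhizal, bm4 control and bm4 mycorrhizal plants. As an example of the second, gst6 had means of 5.36, 9.51, 5.12 and 6.95 in the same order.

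**Figure D2:**
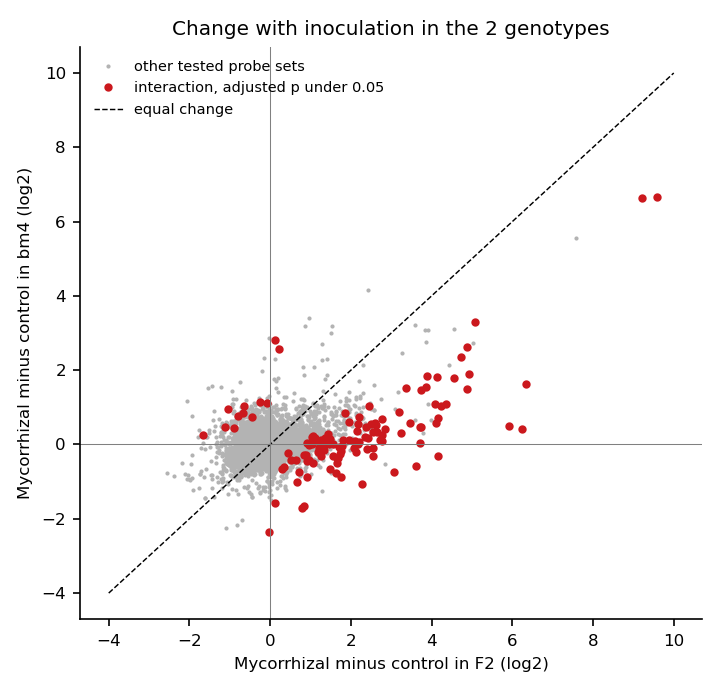
Log2 difference between mycorrhizal and control plants in F2 (horizontal axis) and in bm4 (vertical axis), with 1 point per tested probe set and a dashed line at equal change. The 121 probe sets that passed the interaction test are in red, and 109 of them had a lower value in bm4 than in F2 and lie below the line.

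Detoxification and isoprenoid genes led the lists of the interaction. Of 32 detoxification genes 5 were below 0 and passed, 0 were above and 27 did not pass, or 9 were below adjusted over the list alone, with an adjusted p of 0.000955. Of 9 isoprenoid genes 3 passed below 0, CCD1, Hds1 and dxr (-0.86), and 6 did not pass, or 4 passed adjusted over the list alone, with an adjusted p of 0.00136. Both lists had adjusted p = 0.335 with an estimated correlation. The interaction of psy2 was -0.15 (adjusted p = 0.942) and did not pass. Of 6 defence genes chn1 passed below 0 and 5 did not pass, or 2 passed adjusted over the list alone, with an adjusted p of 0.0266, and adjusted p = 0.494 with an estimated correlation. At the preset correlation, aquaporins had higher responses in bm4 than in F2 as a group (camera adjusted p = 0.00951). Of 23 genes 18 were above 0, with a median of 0.45, and the list had adjusted p = 0.596 with an estimated correlation. The 1 aquaporin gene that passed, NIP1-1, went the other way.

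The defence call of the interaction ended without F2 control array 2 (adjusted p = 0.0712), F2 mycorrhizal array 2 (0.0807), bm4 control array 1 (0.0551) or bm4 mycorrhizal array 2 (0.077), and without cross-hybridising probe sets (0.0929). The aquaporin call ended without F2 control array 1 (0.0636), F2 mycorrhizal array 1 (0.0522) or bm4 mycorrhizal array 2 (0.0578). In the other lists 0 or 1 member passed, and their adjusted p-values ran from 0.0674 for cellulose synthesis to 0.966 for anaerobic genes. The jasmonate list had a median of 0.03 and the ethylene, gibberellin and abscisic acid list one of -0.40, while camera gave them the opposite directions, with adjusted p-values of 0.446 and 0.951. The interaction count was 70 and 42 without F2 control array 1 or 2, 34 and 47 without F2 mycorrhizal array 1 or 2, 19 and 22 without bm4 control array 1 or 2, and 30 and 33 without bm4 mycorrhizal array 1 or 2. No call above 0 was left in 4 of these 8 fits. Among the 10 named calls, that of Hds1 ended in each of these 8 fits. The calls of gst6, CYP88A1, chn1, prpl35-1, NIP1-1 and CCD1 ended in 7 of them, that of gst5 in 3 and that of gst42 in 2. The call of gst30 alone stayed in each. The highest adjusted p-values of the others were 0.0556 for gst42, 0.177 for gst6, 0.105 for CYP88A1, 0.0582 for gst5, 0.16 for NIP1-1 and 0.152 for CCD1 without bm4 control array 1, and 0.186 for chn1, 0.164 for prpl35-1 and 0.139 for Hds1 without bm4 control array 2.

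The genotypes were then compared in control plants, to show how mutant roots differed without inoculation. In bm4, gst30 was 49.8-fold higher than in F2 (5.64 ± 0.13, adjusted p = 1.36e-06) and opr1, an oxophytodienoate reductase, 42-fold (5.39 ± 0.40). The hemoglobin gene Hb was at least 20.6-fold higher, with means of 8.37 in bm4 and 2.81 in F2. The cell wall gene xet1, a xyloglucan endotransglucosylase, was 21.7-fold higher, and sip1 25.1-fold at its brighter probe set, while the other sip1 probe set was 3.07 higher. Lower in bm4 were zrp4 (-2.32 ± 0.29), the glycine-rich protein gene grp3 (-2.30 ± 0.41), the tubulin gene tua5 (-2.09 ± 0.24) and an1, an enzyme of early gibberellin synthesis (-2.07 ± 0.29). Lower too were prpl35-1 and INO1, at -2.14 ± 0.23 and -2.05 ± 0.30, the latter at least 2.12-fold.

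In all, 2514 of 10648 probe sets passed, 1133 higher and 1381 lower in bm4, and 565 and 607 of them were at least 2-fold apart. Which direction had more calls depended on single arrays: without F2 control array 2, or without bm4 control array 2, more were higher than lower. The higher ones included 114 named genes and the lower ones 101. The actin measure of RNA quality given above differed by -0.815 between the control plants of the genotypes, with 2 arrays each and no test. A probe set of pdk1 was 21.8-fold higher and 2 others 14.3-fold and 12.9-fold (adjusted p = 0.00457 and 0.00781), while the brightest probe set of that gene had a value of -0.10 (adjusted p = 0.726). The nas1 probe set of the largest difference was 17.1-fold higher, and the brightest nas1 probe set was 1.94 higher.

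Every one of the 6 defence genes was higher in bm4 control roots, and 6 passed adjusted over the list alone. The wound-induced proteinase inhibitor gene wip1 was 20.4-fold higher (4.35 ± 0.85), PR-5 at least 6.55-fold, the chitinase gene chn1 13.6-fold (3.76 ± 0.25) and PR-1 higher by 3.44. The camera adjusted p was 0.000337, and adjusted p = 0.429 with an estimated correlation. Of 32 detoxification genes, 14 were higher, 1 was lower and 17 did not pass, with the same counts adjusted over the list alone. Besides gst30, GST39 was higher by 3.59 ± 0.22 and gst5 by 3.04 ± 0.17, and the lower one was the catalase gene cat2 (-1.31, with both groups under 4). Among the higher ones gst8 was near background, with means of 3.92 in bm4 and 2.14 in F2 control plants. That list had an adjusted p of 0.00141, and adjusted p = 0.335 with an estimated correlation.

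Cellulose genes were lower as a group. Of 10 genes of cellulose, callose and hemicellulose synthesis, 5 were lower and 5 did not pass, or 8 were lower adjusted over the list alone, and all 10 had values below 0. The brittle stalk gene bk2, a COBRA-like gene needed for stem strength, was at -1.82 ± 0.27, and the cellulose synthase genes cesa8 and cesa2 were at -1.24 ± 0.30 and -1.12 ± 0.26. The camera adjusted p was 0.00951, and adjusted p = 0.596 with an estimated correlation. Of 15 anaerobic genes 7 were higher, 0 lower and 8 did not pass, with 7 adjusted over the list alone. Besides Hb they included the aldehyde dehydrogenase gene aldh2 (2.99 ± 0.36) and the pyruvate decarboxylase gene pdc2 (2.25 ± 0.47 at the named probe set, and 1.37 at the brightest). The adjusted p was 0.0218, and adjusted p = 0.429 with an estimated correlation, and the call ended without F2 control array 1 (0.0613) and with the filter at 6 (0.0519).

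**Figure D3:**
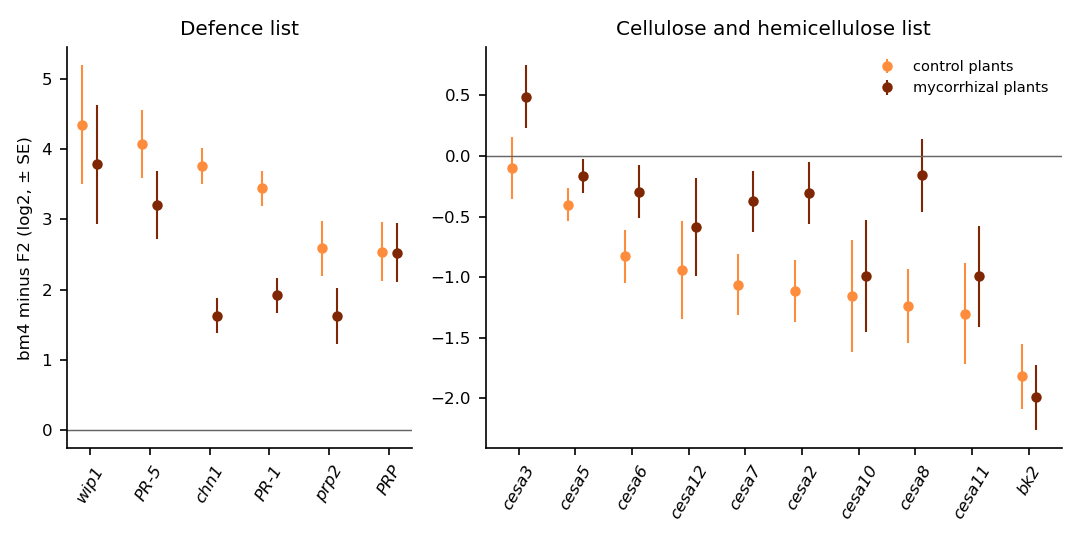
Log2 difference between bm4 and F2 (vertical axis, points with ± SE) for 6 defence genes and 10 genes of cellulose, callose and hemicellulose synthesis, in control and in mycorrhizal plants. The 6 defence genes lay above 0 in both conditions, and bk2 lay at -1.82 and -1.99.

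Of the 5 monolignol genes 2 were higher in bm4 and 3 did not pass, with 2 adjusted over the list alone: ccr2 by 1.07 ± 0.16 and bm1 by 0.65 ± 0.14 (adjusted p = 0.0152), with a list adjusted p of 0.154. Of 6 lignin polymerisation genes, 1 was higher, ap1 (1.11), and 1 lower, the peroxidase gene PER2 (-1.74), with a list adjusted p of 0.833. Of 5 genes of ethylene, gibberellin and abscisic acid 4 were higher and an1 was lower. The ethylene response factor gene ERF1 was at least 2.42-fold higher and acco20, named for the enzyme that makes ethylene, 3.48-fold, with a list adjusted p of 0.105. Of 6 metal homeostasis genes 3 were higher, nas1, the ferritin gene fer1 (1.04 ± 0.25) and DMAS1 (0.54 ± 0.14), with a list adjusted p of 0.0722. Of 10 genes on the jasmonate list 3 were higher, opr1, the lipoxygenase gene lox3 (1.56) and opr5 (1.40), and aoc1 was lower (-0.79), with a list adjusted p of 0.154. They were matched by symbols such as opr and lox, which does not establish a part in jasmonate synthesis.

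Isoprenoid genes split, with tps6 (4.04), Hds1 (1.51) and dxr (0.91) higher, and psy2 (-1.98), zds1 (-1.03) and Pds (-0.61) lower (list adjusted p = 0.585). Of 23 aquaporin genes 3 were higher, among them TIP3-1 with both groups under 4, and 8 lower (list adjusted p = 0.122). Of 7 sugar genes 2 were higher and 1 lower (0.345). Of 8 nitrogen genes 1 was higher, asn1 (1.67), and 1 lower, gln5 (-0.64), with a list adjusted p of 0.957. Of 7 wall loosening genes xet1 was higher and expB4 lower (-2.02), with a list adjusted p of 0.578. Among 12 cell division genes 2 were lower (0.223), among 14 ribosomal proteins 1 was higher and 1 lower (0.225), among 10 heat shock genes 2 were higher and 1 lower (0.941), and among 7 proteases 0 passed (0.941). The heat shock list had a median of -0.07, while camera gave it an upward direction. Of the untested small lists, 2 of 3 benzoxazinoid genes were lower, bx6 (-1.11) and igl1 (-0.60), as was 1 of 3 lipid genes, gl8 (-0.64), and 0 passed among 3 auxin, 2 photosynthesis, 2 phosphate and 2 mycorrhiza marker genes and 1 folate or methyl cycle gene.

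The count in control plants was 1464 without F2 control array 2, 1515 without bm4 control array 1 and 1087 without bm4 control array 2. Of 29 named calls 22 stayed when any 1 array was left out. Without bm4 control array 1, wip1 had an adjusted p of 0.0645, bm1 0.0853, pdc2 0.0761, fer1 0.126 and DMAS1 0.128, and without bm4 control array 2, cesa2 had 0.102 and cesa8 0.149. These 7 lost their calls without the other bm4 control array too, wip1, cesa2, cesa8 and fer1 also without F2 control array 2, and DMAS1 without either F2 control array.

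The genotypes were compared in mycorrhizal plants as well. There a probe set of nas1 was 66.6-fold higher in bm4 (6.06 ± 0.39, adjusted p = 0.000153), and the brightest nas1 probe set was 3.59 higher (adjusted p = 0.000243). Hb was at least 29.3-fold higher, opr1 21-fold (4.39 ± 0.40) and xet1 10.5-fold (3.39 ± 0.41). The plastid ribosomal protein gene prpl35-1 was lower by the most among named genes, at -4.19 ± 0.23. The genes gst6 (-2.56 ± 0.27), ciszog1 (-2.40 ± 0.39) and CYP88A1 (-2.25 ± 0.21), each of which rose with inoculation in F2, were lower in bm4 here. MADS67, a MADS-box gene, and cat2 were at -2.43 ± 0.35 and -2.31 ± 0.39. In bm4 the signal of CYP88A1 and cat2 was under 4, which makes them at least 1.32-fold and 1.81-fold lower.

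In all, 1662 probe sets passed, 803 higher and 859 lower, with 467 and 405 of them at least 2-fold apart, and with 90 named genes higher and 63 lower. Which direction had more calls was not stable. With each array centred on its median 852 were higher and 812 lower, and without either F2 mycorrhizal array more were higher than lower too. The actin measure differed by -0.575 between the mycorrhizal plants of the genotypes, again with 2 arrays each and no test. A probe set of pdk1 was 27.6-fold higher and 2 others 14.7-fold and 5.26-fold (adjusted p = 0.0119 and 0.0487), while the brightest pdk1 probe set had a value of -0.62 (adjusted p = 0.0564).

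The 6 defence genes were higher again, and 6 passed adjusted over the list alone, with wip1 13.8-fold higher (3.79 ± 0.85), PR-5 at least 6.02-fold and PRP 5.76-fold (2.53 ± 0.42). The camera adjusted p was 0.000955, and adjusted p = 0.429 with an estimated correlation. Of 6 metal homeostasis genes 3 were higher and 3 did not pass, with 3 adjusted over the list alone. They were nas1, ys1, which takes up iron bound to phytosiderophores (1.98 ± 0.28), and DMAS1, which makes the phytosiderophore deoxymugineic acid (1.25 ± 0.14). That list had an adjusted p of 0.0266, and adjusted p = 0.429 with an estimated correlation. Of 15 anaerobic genes 6 were higher, 1 lower and 8 did not pass, with the same counts adjusted over the list alone. Hb2 was at least 2.9-fold higher, aldh2 was higher by 2.50 ± 0.36 and adh1 by 1.64, and sh1 was lower (-0.58). Its adjusted p was 0.0403, and adjusted p = 0.47 with an estimated correlation. The anaerobic call ended without bm4 mycorrhizal array 1 (0.0574), with the filter at 6 (0.0879) and with the mean of each gene's probe sets (0.059).

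Ribosomal protein genes were slightly lower in mycorrhizal bm4 roots, with a list median of -0.25. Of 14, 2 were lower and 12 did not pass, or 4 were lower adjusted over the list alone. They included rps13 (-0.40 ± 0.10) and rpl30 (-0.40 ± 0.08), and a second probe set of RPL10 went the other way, at 0.67 ± 0.09, while its brightest had a value of 0.02. The adjusted p was 0.0199, and adjusted p = 0.47 with an estimated correlation.

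Of 32 detoxification genes 9 were higher and 4 lower, or 10 and 4 adjusted over the list alone, with gst30 8.04-fold and GST39 5.52-fold higher and a list adjusted p of 0.0604. Of 9 isoprenoid genes 4 were lower, psy2 (-2.13), zds1 (-1.45), Pds (-0.96) and CCD1 (-0.95), with a list adjusted p of 0.125. Of 10 cellulose genes bk2 alone was lower (-1.99, list adjusted p = 0.125). Of 5 monolignol genes ccr2 was higher by 0.60 ± 0.16, and bm1, at 0.38 ± 0.14, did not pass (adjusted p = 0.12), with a list adjusted p of 0.381. In the list of ethylene, gibberellin and abscisic acid, ERF1 was at least 3.34-fold and acco20 2.63-fold higher and an1 was lower (-1.05 ± 0.29), with a list adjusted p of 0.106. The remaining tested lists had adjusted p-values from 0.174 for proteases to 0.873 for sugar genes.

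The count in mycorrhizal plants was 855 without F2 mycorrhizal array 1, 976 without F2 mycorrhizal array 2 and 756 without bm4 mycorrhizal array 1. Of 27 named calls 18 stayed when any 1 array was left out. Without bm4 mycorrhizal array 1, the adjusted p was 0.133 for wip1, 0.0576 for PRP, 0.0511 for ciszog1, 0.0583 for cat2, 0.0583 for acco20, 0.264 for an1, 0.222 for ccr2 and 0.192 for rps13, and without F2 mycorrhizal array 2 it was 0.112 for rpl30. The calls of PRP and ciszog1 ended without bm4 mycorrhizal array 1 alone, and those of the other 7 without further arrays as well.

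The genotype differences in control and in mycorrhizal plants overlapped. Of the higher probe sets 602 passed in both, where independent lists would share 85.4, and of the lower ones 506, where 111 would be shared, while 22 passed in opposite directions. Across all tested probe sets the differences correlated with r = 0.783. As a mean over both conditions, 3520 probe sets passed, 1510 higher and 2010 lower in bm4. The higher named genes of the rule were nas1 (33.8-fold at 1 probe set, and 2.76 on the log2 scale at the brightest), opr1 (29.7-fold), gst30 (20-fold, 4.32 ± 0.09) and Hb (at least 24.6-fold). The lower ones were prpl35-1 (-3.16 ± 0.17), MADS67 (-2.16 ± 0.25), psy2 (-2.05 ± 0.20) and bk2 (-1.91 ± 0.19). These 8 calls stayed when any 1 array was left out, and the count was 2345 without bm4 mycorrhizal array 1.

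As a mean over both genotypes, inoculation changed 652 probe sets, 406 higher and 246 lower. The named genes with the largest rises were ciszog1 (9.75-fold, 3.29 ± 0.28), gst6 (7.93-fold), psy2 (4.66-fold) and tps6 (4.34-fold). Those with the largest falls were nrt2, HP3, PDK2 and pdrp1, which fell by 1.46 ± 0.28, 1.08 ± 0.22, 1.07 ± 0.19 and 0.77 ± 0.17. The count was 320 and 382 without F2 mycorrhizal array 1 or 2, 347 and 355 without bm4 control array 1 or 2, and 337 and 379 without bm4 mycorrhizal array 1 or 2. The 246 lower calls went down to 77 without F2 mycorrhizal array 1. The first 3 of the named rises stayed in each fit with 1 array left out. The calls of tps6, nrt2 and HP3 ended without bm4 control array 1 (adjusted p = 0.0737, 0.0959 and 0.105), and those of PDK2 and pdrp1 without F2 mycorrhizal array 1 (0.0789 and 0.134), among other arrays.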

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

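In this part, the tests on the smaller rise in bm4 and on the higher level of F2-induced genes in bm4 controls were chosen after the results were seen; the interaction itself was planned. The response to inoculation differed between the genotypes in 121 probe sets by the interaction test. Of the 13 named genes among them, the 10 taken by the naming rule were gst30 (-2.63), gst42 (-2.51), gst6 (-2.31), CYP88A1 (-2.16), gst5 (-2.14), chn1 (-2.13), prpl35-1 (-2.05), NIP1-1 (-1.66), Hds1 (-1.31) and CCD1 (-1.13). The count fell to between 19 and 70 when 1 array was left out, as given for each array in the results. The lists that differed, with their camera adjusted p at the preset correlation, were defence (0.0266), isoprenoid genes (0.00136), aquaporins (0.00951) and detoxification (0.000955). None of these lists passed with an estimated correlation. With groups of 2 arrays, single arrays were not tested as outliers.

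Rises with inoculation were smaller in bm4: over the 406 probe sets that rose in the mean of both genotypes, a choice that leaves the difference between them free, the median change was 1.30 in F2 and 0.47 in bm4, the change was larger in F2 for 88.4% of them, and the ratio of medians was 0.359, while the 246 that fell differed less, with medians of -0.63 and -0.485 and a larger fall in F2 for 65.9%. More noise in the bm4 arrays would not lower a median, and the SD between arrays of a group was no wider in bm4 (0.32 and 0.31) than in F2 (0.40 and 0.34), so noise is argued against for the rises. The same response in a smaller share of the tissue may still account for part of it: with a common ratio of 0.158 taken from 219 of the probe sets that rose in F2, predicted and measured changes in bm4 over the other 219 correlated with r of 0.742 and at least 0.673, depending on the control array used. But 71.2% lay within 2 SE of that prediction against 54.8% for no change, with 24 above and 39 below, so it cannot be told apart from a response that differs between genes. No colonization level was given, and an effect of the mutation on the response itself remains open and untested.

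Genes that the fungus induced in F2 were often already higher in bm4 controls: 164 of 438, where independent lists would share 46.6, and 52 were lower, where 56.8 would be shared. With F2 control array 1 used for inoculation and array 2 for genotype, no array entered both differences. The covariance of the changes across probe sets was then 0.0836, and it was 0.114 with the arrays exchanged. With both arrays in both comparisons, the covariance of the changes was 0.139, while 20 simulations of unchanged groups against those controls gave a mean of 0.0298 and at most 0.0333 (r was 0.319, and 0.495 on average when simulated), so shared controls are argued against as the whole cause, though part of the excess may come from them or from a deviation common to both control arrays. For fungus in the bm4 control pots, 22 probe sets were used that were raised at least 4-fold in F2. Their mean was under 3 in F2 controls, a lower level than the 4 used elsewhere. Their median difference between bm4 and F2 controls was 0.0101 (quartiles -0.0358 and 0.128), and 3 of them passed as higher. This median cannot decide, because many of them, chosen by their rise in F2, rose little in inoculated bm4 too. The 2 with the largest rises in bm4 went from 2.44 to 9.10 and from 2.32 to 8.97 there. In F2 controls they had 2.38 and 2.28, so these 2 show no sign of fungus in bm4 controls. Another of the 22 went the other way, with 9.57 in bm4 controls and 2.74 in F2 controls. A constitutive stress or defence state of bm4 roots stays open as a hypothesis, untested.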

How the results depend on the processing

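Fits without cross-hybridising probe sets, and without list members matched through another gene's name, were added after the data were seen. Of 142 counts of calls under alternatives, 107 stayed within 1.5 times the reported one. Scaling or centring the arrays again moved no share of higher calls by over 10 percentage points. Other than by leaving out an array, the count moved to 325 in F2 and to 17 in bm4 when only the 4 arrays compared were fitted, and in bm4 to 79 with the filter at 6 and to 80 with array weights. With 4 arrays there were fewer degrees of freedom; for the filter and the weights the cause was not tested. The list calls went from 23 to 0 with an estimated correlation, where camera, by its construction, tests with the residual degrees of freedom of the arrays. The estimated correlation was also far above the preset 0.01 for some lists. It was 0.683 for cellulose, 0.588 for monolignol, 0.566 for protease, 0.492 for nitrogen, 0.417 for aquaporin and 0.291 for defence genes. For others it was lower, at 0.00642 for detoxification, -0.0129 for sugar and -0.11 for isoprenoid genes. Even so, the camera adjusted p went from 1.13e-05 to 0.335 for isoprenoid genes in F2. For detoxification genes between control plants it went from 0.00141 to 0.335. These values argue against a correlation above the preset as the cause of the lost calls of the detoxification, sugar and isoprenoid lists. For lists with an estimated correlation above the preset, the 2 effects were not separated.

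Leaving out 1 array gave 254 to 525 calls for inoculation in F2, 10 to 51 in bm4, 1087 to 2281 for bm4 against F2 in control and 756 to 1699 in mycorrhizal plants, 19 to 70 for the interaction, 320 to 591 and 2345 to 3476 for the mean contrasts of inoculation and genotype, and 21 to 28 list calls. Each such fit also had fewer arrays. The 115 results for named genes had 2021 values under alternatives: 1732 kept their side of the threshold, 287 did not pass any more (216 of them with 1 array left out), 2 passed newly and 0 changed direction. The 2 were those of bm1 between mycorrhizal plants without either F2 control array (lowest adjusted p = 0.0458). In all, 67 of the 115 kept their call under every alternative run.

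The labels give all groups the replicate numbers 1 and 2, and deviations of same-numbered arrays correlated between -0.0947 and 0.242, over 0.1 in 3 of 6 pairs of groups, so the arrays were not taken as paired. With the replicate block the counts were 581, 47, 2312, 1548, 93, 558 and 3322, in the order F2, bm4, control, mycorrhizal, interaction, mean inoculation and mean genotype, and 26 list calls passed. Robust estimation could not be run for camera, which has no such option.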

Other observations

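The tests of second probe sets and of other splits were planned before their results were seen, and the count of genes on or off by genotype and the division of second probe sets by sequence were chosen after. Some genes were nearly on or off by genotype. With a level under 4 in both groups of one genotype and over 6 in both groups of the other, 29 probe sets were off in F2 and on in bm4, and 9 the reverse.

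Sequence differences between the F2 and bm4 lines under single probes could give such differences with no change in expression, which second probe sets can test. For 60 genes with a probe set that passed between the genotypes, 54 second probe sets (90%) had the same direction, 37 of them passed too, and 2 passed the other way (exact binomial two-sided p = 9.72e-11 against an even share, with genes taken as independent). But 37 of these genes had a second probe set with the sequence identifier of the first, which a sequence difference could move as well, and of 33 with another identifier, whose sequences may still overlap, 30 had the same direction (90.9%). With another cluster of sequences 4 of 6 had it (exact binomial p = 0.687), so without probe sequences the 2 causes cannot be told apart. Whether the difference comes from the bm4 gene or from other parts of the genome by which the lines may differ was not tested. The actin 3′ minus 5′ signal, smaller in bm4 without passing after adjustment, cannot be separated from genotype with 4 arrays each.

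Whether chance could give such counts was tested with other splits of the 8 arrays into 4 and 4, in a model with the other factor kept. For the genotype difference the real split gave 3152 probe sets, the highest of the others 0, and 1 of 34 splits, the real one, gave as many. For inoculation the real split gave 217, the highest of the others 0, and again 1 of 34 splits, the real one, gave as many. In the other splits the real factor stayed at least in part in the residual spread, which lowers their counts. The 0 therefore does not show how many calls chance alone would give. The share of 1 in 34 is the smallest that 34 splits can give, and it argues against chance only if the arrays of a group are independent samples, which the labels do not state.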
